A study of Homo sapiens with 9 samples.

How the data were processed

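RNA was measured in 9 libraries of MDA-MB-231 cells, an established human triple-negative breast cancer line of mesenchymal character. Per the labels' protocols, stable lines were made with lentivirus and selected with puromycin at 1 µg/mL, total RNA was taken with TRIzol, and poly(A) libraries were sequenced on an Illumina NovaSeq. The 3 groups have 3 libraries each: empty vector, overexpression of FOXA1 and overexpression of FH. The labels do not spell out FH, which is used both as an abbreviation of the forkhead DNA-binding domain of FOXA1 and as the symbol of the fumarate hydratase gene.

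The values deposited by the authors are read counts, whole numbers that were not normalized. Per the file headers, they were made with featureCounts 1.6.3 on GENCODE release 42 in a mode that keeps 1 row per exon of each transcript, without strand, without pairing of mates and without counting reads that overlap more than 1 row. Alignment with HISAT2 to hg38 is named in the submitters' processing notes, with no version. Each file has 1763340 exon rows under 62808 gene names. Of these rows, 71.7% share all coordinates with another row, and such rows held 0 counts in the 9 libraries together. A gene's count therefore covers only bases that lie under exactly 1 exon row. For protein-coding genes the median share of such bases was 41.0%, and 117 of 19069 had no such base. Counts of a gene can thus come mainly from a 3' end, from a rare transcript or from rows annotated as retained introns, and levels of different genes are not comparable. Where over 30% of a gene's counts fell in retained-intron rows, that share is given beside the gene's log2 change. Because the counting ignored strand, reads of overlapping antisense genes cannot be told apart.

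Exon rows were summed per gene name. Counts per library ran from 5659271 to 7014556, of which 33.3% to 34.8% were mitochondrial, and 20042 to 21215 genes had at least 1 count. In edgeR 4.0.16 under R 4.3.3, genes were kept by filterByExpr with a minimum count of 10, which left 12578. TMM factors were applied, and the quasi-likelihood test was fitted to all 9 libraries with group as the only term. P-values were adjusted by the Benjamini-Hochberg method over the genes of a comparison, and a gene was called at an adjusted p under 0.05. Levels are TMM-normalized CPM (a gene's counts scaled to library size), given as mean ± SD with n = 3. Log2 changes are given ± SE. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical. If each group is 1 stable line, a difference between lines cannot be told apart from a response to a construct. Every pair of replicates differed by more than the noise of independently counted reads, with a chi-square per degree of freedom from 2.72 to 4.56 over genes. Mates were not paired in counting, so a fragment may add more than 1 count, which would raise these values.

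Fixed before the data were examined were the comparisons, the test, 16 gene lists, the alternatives and the rule for naming genes. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the 14 lists with at least 2 tested members. Camera with an estimated correlation was the alternative, and of the 9, 2 and 4 lists called for FOXA1 against vector, FH against vector and FOXA1 against FH, 6, 1 and 3 held with it. Calls of lists are those of camera. Fry, fixed beside it, asks whether members changed at all, not whether they changed more than other genes. Every list called by camera had a fry adjusted p under 0.05. So did basal with FOXA1 (0.015), and basal and inflammatory with FH (0.047 each). For FOXA1 against FH so did stress (0.0028), androgen receptor (0.0053), epithelial (0.021), interferon (0.041) and mesenchymal (0.045). The lists cover luminal and basal breast identity, epithelial junctions, mesenchymal state, invasion proteases, interferon response, inflammatory cytokines, proliferation, foregut and liver, androgen receptor targets, stress response, hypoxia, cholesterol synthesis, YAP and TEAD targets, and 2 sets of markers of other cell types. Tested were 9 of 25 luminal, 9 of 25 basal, 9 of 28 epithelial, 13 of 30 mesenchymal and 8 of 16 protease members. So were 12 of 30 interferon, 12 of 24 inflammatory, 23 of 26 proliferation, 6 of 30 foregut and 4 of 15 androgen receptor members. The stress list had 18 of 22, hypoxia 17 of 25, cholesterol 14 of 23, and YAP and TEAD 19 of 22. Each set result covers only the tested members. For each comparison the rule names FOXA1 and FH, and the 10 largest rises and 10 largest falls among called genes with at least 5 CPM in the higher group and no overlap between the groups. It also names up to 4 called members of each called list and up to 2 of each other list. Clones, antisense genes and pseudogenes are left out, and some genes that the rule names are not reported here.

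Alternatives were size factors of DESeq2, no filter, the replicate number as a block, fits of only the 6 libraries compared, the counts without FOXA1 and FH, the DESeq2 1.42.0 Wald test, a silence limit of 0.5 CPM, genes of at least 5 CPM for similarity, and each library left out in turn. Chosen after seeing the data were protein-coding transcript rows alone, the counts without mitochondrial genes, a loess offset against abundance, similarity over the genes that passed the filter in each simulation, and similarity with separate vector libraries. Similarity of the responses was set beside 50 simulations of unchanged groups against the same vector libraries. The fit was tested on simulated counts for FOXA1 against vector. There, 200 of 12578 genes were changed, all drawn from genes above 2 CPM with vector. The other tested members of the luminal list were raised 1.5-fold. At 10 CPM or more, 93.3% of the 2-fold changes and 55.8% of the 1.5-fold changes were found. Over all drawn genes that passed the filter the shares were 52% and 28%, with 4 of 88 calls on unchanged genes. Genes at 2 CPM or less were not drawn. For FOXA1 against FH in the same simulated counts these shares were 88.9% and 67.4%, and 51% and 32%, with 8 of 95 calls on unchanged genes. Small changes of low genes are therefore often missed at this depth. Coding positions of FOXA1 and FH came from the GENCODE annotation of hg38 at hand, an older release than the files use. Tables were made with Python 3.11.15, pandas 2.3.3 and scipy 1.17.1.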

Results

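Gene expression was compared between MDA-MB-231 cells carrying an empty lentiviral vector, cells overexpressing FOXA1, a forkhead pioneer transcription factor of luminal breast, liver and prostate cells, and cells overexpressing the construct labelled FH. The series title concerns phase separation of FOXA1 and the unpacking of condensed chromatin. Each group had 3 libraries, and libraries had 5659271 to 7014556 counts. In a principal component analysis the first component, with 19.0% of the variance, put the FH libraries between the vector and FOXA1 libraries. The second, with 15.2%, set the FH libraries apart from both other groups.

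The overexpressed sequences could not be seen in these counts. FOXA1 lies on chromosome 14, 37589552 to 37596059 (hg38, minus strand). All 1416 coding bases of its main transcript lie under more than 1 of its 11 exon rows or under none, so 0 of them could be counted. Most FOXA1 counts came from the exon row holding the 1541 countable bases from 37589552 to 37591092, which lie beyond the stop codon at 37591365 to 37591367, in the 3' untranslated part. A construct without that sequence adds nothing to them. FOXA1 stood at 11.3 ± 1.43 CPM (SD, n = 3) with vector, 8.53 ± 0.783 with FOXA1 and 7.05 ± 1.69 with FH. Its log2 change was -0.41 ± 0.25 (SE, adjusted p = 0.40) with FOXA1 and -0.68 ± 0.25 (adjusted p = 0.12) with FH, and FOXA1 libraries differed from FH libraries by 0.27 ± 0.25 (adjusted p = 0.72). The gene FH, fumarate hydratase on chromosome 1, 241497511 to 241519799, had 0 of 1530 coding bases countable, and 56.0% of its counts fell in retained-intron rows. It had 18.0 ± 3.21 CPM with vector, 18.4 ± 3.12 with FOXA1 and 15.98 ± 2.52 with FH, log2 changes of 0.03 ± 0.19 (adjusted p = 0.96) with FOXA1 and -0.18 ± 0.19 (adjusted p = 0.72) with FH, and a difference of 0.21 ± 0.19 (adjusted p = 0.70) between them. The check of the labels by the overexpressed gene is therefore void, and these values do not show which sequence FH names.

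**Figure D1:**
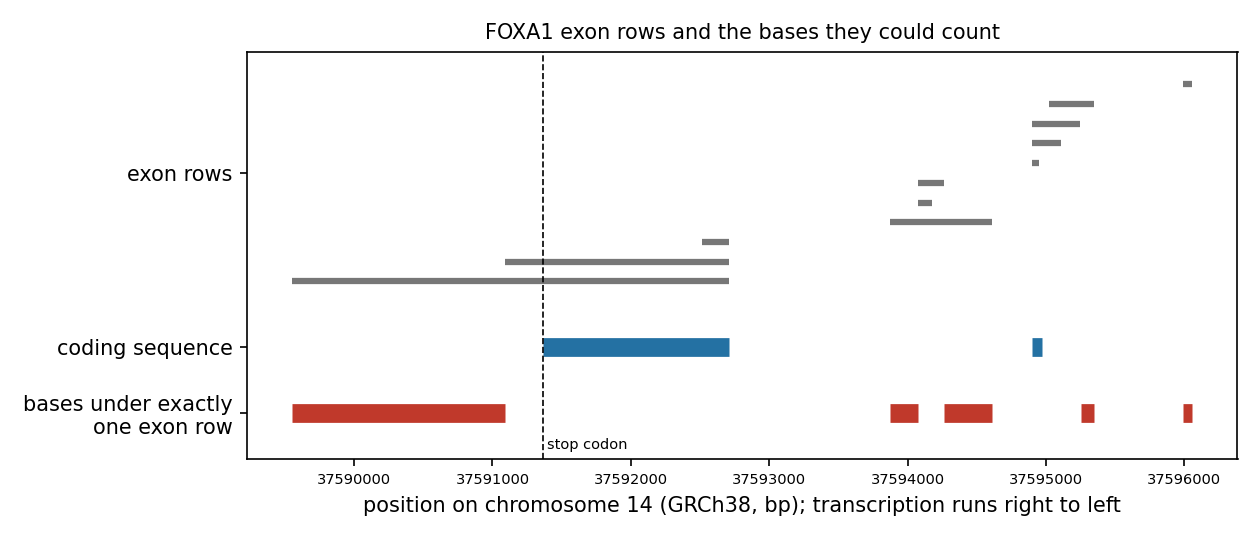
Exon rows of FOXA1 (grey), coding sequence of its main transcript (blue) and bases under exactly 1 exon row (red), by position on chromosome 14 in bp. The red stretches, the longest of 1541 bases beyond the stop codon, share 0 bases with the coding sequence.

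The comparison of FOXA1 with vector asks what changed in cells overexpressing FOXA1. Inflammatory cytokine genes fell. IL1B, which encodes interleukin-1 beta (chromosome 2, 112829751 to 112836816), went from 47.3 ± 2.55 CPM with vector to 4.92 ± 2.20 with FOXA1 (SD, n = 3), a log2 change of -3.27 ± 0.20 (adjusted p = 1.0e-17). The neutrophil chemokine gene CXCL1 (chromosome 4, 73869393 to 73871308) changed by -2.48 ± 0.20 and IL1A by -2.48 ± 0.37 on the log2 scale. Targets of the growth regulators YAP and TEAD rose, and ANKRD1 (chromosome 10, 90912096 to 90921087) went from 936 ± 33.6 to 1990.2 ± 59.2 CPM. In all, 840 genes were called, 391 higher and 449 lower, and 62 rose and 123 fell at least 2-fold. Without vector replicate 1, 559 genes were called, and with protein-coding transcript rows alone 116 changed at least 2-fold.

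In the list of NF-kB and inflammatory cytokine genes, 0 of 12 tested members rose and 5 fell (7 when adjusted over the list alone), and the list fell as a set (adjusted p = 1.1e-12). Besides IL1B, CXCL1 and IL1A these were CXCL2 with -1.03 ± 0.21 and the adhesion receptor ICAM1 with -0.75 ± 0.21, named after its value was seen. Of 19 YAP and TEAD targets, 7 rose and 1 fell (8 and 2 adjusted over the list alone), and the set rose (adjusted p = 1.5e-07). ANKRD1 changed by 1.09 ± 0.05, the matricellular gene CCN2 by 0.58 ± 0.04 and CRIM1 by 0.42 ± 0.05, whereas PTPN14, a phosphatase that restrains YAP, changed by -0.38 ± 0.04. Of 18 genes of the unfolded protein and integrated stress response, 8 rose and 1 fell (8 and 2 adjusted over the list alone), and the set rose (adjusted p = 5.4e-04). The stress-induced gene SESN2 changed by 0.65 ± 0.11, the serine synthesis gene PSAT1 by 0.48 ± 0.07 and SDF2L1, of the endoplasmic reticulum, by 0.57 ± 0.12. The transcription factor gene CEBPB changed by -0.38 ± 0.05.

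The invasion protease list also holds inhibitor genes such as TIMP2 and the receptor gene PLAUR, so its result is not one of proteases alone. Of its 8 tested members, 0 rose and 3 fell (4 adjusted over the list alone), and the set fell (adjusted p = 8.0e-06). The collagenase gene MMP1 went from 105 ± 1.73 to 50.9 ± 3.72 CPM, a log2 change of -1.04 ± 0.10 (adjusted p = 4.7e-11). The stromelysin gene MMP3 changed by -3.90 ± 0.61 from 5.15 CPM, and TIMP2, an inhibitor of such enzymes, by -0.26 ± 0.08. The interferon list fell (adjusted p = 0.0057) with 3 of 12 members called, or 5 adjusted over the list alone. These were DDX58 (-1.05 ± 0.28, 95.9% of counts in retained-intron rows), IFI44 (-1.44 ± 0.43) and IRF1 (-0.93 ± 0.30, 40.9%). The hypoxia list fell (adjusted p = 0.0070) with 2 of 17 called, the same number adjusted over the list alone. These were the vessel growth factor VEGFA (-1.48 ± 0.12, 98.8% of counts in retained-intron rows) and the glycolytic regulator PFKFB4 (-0.47 ± 0.12). With protein-coding transcript rows alone the interferon list had adjusted p = 0.33 and the hypoxia list adjusted p = 0.35. Without a filter on low counts the hypoxia list had adjusted p = 0.058, and without FOXA1 replicate 2 the interferon list had adjusted p = 0.055.

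Luminal breast identity genes shifted up as a set (adjusted p = 0.023), a call lost with an estimated correlation (adjusted p = 0.079). Of 9 tested members 1 was called, also over the list alone: KRT7, a keratin of simple epithelia, which went from 39.3 ± 4.88 to 87.3 ± 4.11 CPM. ESR1, GATA3, KRT18 and KRT19 were not among the genes tested. The epithelial junction list shifted up (adjusted p = 0.040) and lost its call with an estimated correlation (adjusted p = 0.105). Of its 9 members 1 rose, the tight junction gene CLDN1 (0.63 ± 0.08), and 1 fell, with 4 and 1 adjusted over the list alone. The androgen receptor list shifted down (adjusted p = 0.044) and lost its call with an estimated correlation (adjusted p = 0.105). Of its 4 members 2 fell with both adjustments, among them NDRG1 (-0.97 ± 0.28, 87.2% of counts in retained-intron rows). The luminal call was lost without vector replicate 1 (adjusted p = 0.101) or 3 (0.074), and the epithelial call without vector replicate 1 (0.074) or 3 (0.101) or FOXA1 replicate 1 (0.12). The androgen receptor call was lost in 8 of 9 fits that left out 1 library, all but that without FH replicate 2, with adjusted p up to 0.14 without FOXA1 replicate 3. It was also lost in the fit of 6 libraries (0.060) and without mitochondrial genes (0.066). With protein-coding rows alone the luminal (0.57), epithelial (0.23) and androgen receptor (0.35) calls were lost, and without a filter the luminal (0.065) and epithelial (0.24) calls.

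The other 5 lists were not called. Basal identity had adjusted p = 0.38, with 1 of 9 members called, lower, and 1 higher and 1 lower adjusted over the list alone. The mesenchymal list had adjusted p = 0.80, with 1 higher and 2 lower of 13, among them LOXL2 at -0.26 ± 0.06. Its median log2 change was -0.01 and its mean 0.0019, and its test pointed up. Proliferation had adjusted p = 0.63, with 2 higher and 1 lower of 23, including MKI67 at -0.44 ± 0.11 and E2F1 at 0.25 ± 0.06. Foregut and liver genes had adjusted p = 0.51, with 1 of 6 called, CEBPA at 1.30 ± 0.41. Cholesterol synthesis had adjusted p = 0.63, with 1 of 14 called, SC5D at 0.37 ± 0.10. For the mesenchymal, proliferation, foregut and cholesterol lists, adjustment over the list alone gave the same counts.

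Beyond the lists, SHANK2, a synaptic scaffold gene, had the largest rise among the named genes, from 0.904 ± 0.249 to 12.4 ± 3.07 CPM (log2 change 3.76 ± 0.42, 31.2% of counts in retained-intron rows). RTN4RL1 (2.53), the protease-activated receptor gene F2RL2 (2.35 ± 0.18, from 9.28 to 47.3 CPM), WASHC1 (2.29, uncertain because near-identical copies exist), the Hedgehog effector GLI2 (2.04), ATOH8 (1.99), the glutathione-degrading CHAC1 (1.93), TSPAN33 (1.69), TOX (1.68) and the activin subunit gene INHBB (1.64) followed. The largest falls besides MMP3, IL1B, IL1A and CXCL1 were in SIRPB1 (-3.63, uncertain because of similar family members), the tetraspanin gene CD82 (-2.34), the cholesterol hydroxylase CH25H (-1.96), CST7 (-1.95), IGFN1 (-1.84) and the histone gene H2BC21 (-1.78, uncertain because histone genes are similar). These 20 genes were picked among those whose groups did not overlap. Over all tested genes 22.2% had groups without overlap, against 10% by chance.

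Calls of 10 named genes ended in some of the 9 fits that left out 1 library. TIMP2 lost its call in 6 fits (highest adjusted p = 0.44, without vector replicate 1, where its log2 change was -0.16), IRF1 in 5 (0.33, vector replicate 1), MKI67 in 3 (0.105, vector replicate 1), IFI44 in 5 (0.18, vector replicate 2) and E2F1 in 2 (0.085, vector replicate 3). DDX58 lost it in 1 (0.064, FOXA1 replicate 1), SC5D in 2 (0.14, FOXA1 replicate 1), CEBPA in 6 (0.32, FOXA1 replicate 2), PFKFB4 in 2 (0.100, FOXA1 replicate 2) and NDRG1 in 5 (0.15, FOXA1 replicate 3). TIMP2 also missed the threshold with DESeq2 size factors (0.055) and the Wald test (0.070). IRF1 missed it with the Wald test (0.065), protein-coding rows (0.064) and the loess offset (0.052). Without a filter IFI44 (0.072) and CEBPA (0.096) missed it, as did CEBPA in the fit of 6 libraries (0.063).

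**Figure D2:**
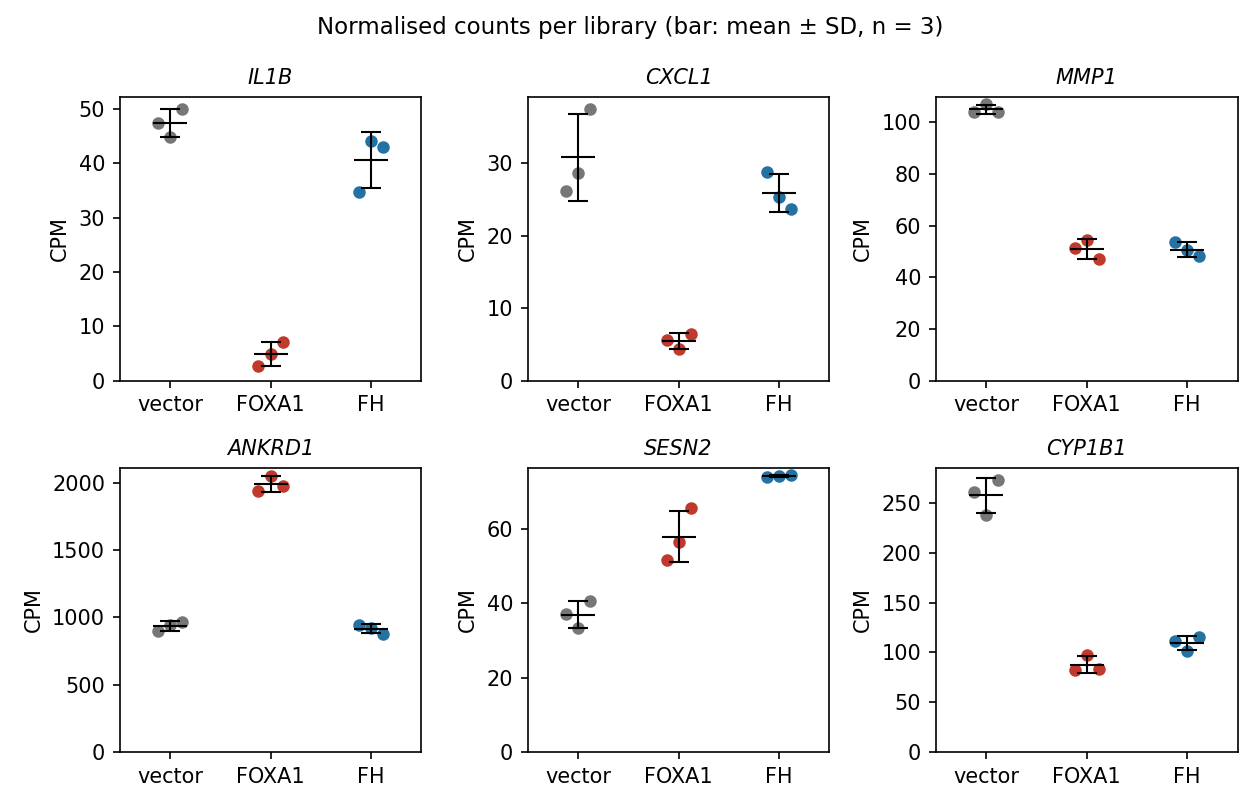
Normalised counts (CPM, linear axes from 0) of 6 genes in each of the 9 libraries, with bars for mean ± SD of n = 3. IL1B and CXCL1 were low and ANKRD1 high in the FOXA1 libraries, whereas MMP1 and CYP1B1 were lower and SESN2 higher in both overexpressing groups than with vector.

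The comparison of FH with vector asks the same of the FH construct. Stress response genes rose. SESN2 (chromosome 1, 28259518 to 28282491) went from 37.0 ± 3.64 CPM with vector to 74.3 ± 0.234 with FH (SD, n = 3), a log2 change of 1.01 ± 0.11 (adjusted p = 1.5e-08), and asparagine synthetase, ASNS, rose by 1.77 ± 0.38 with 69.9% of its counts in retained-intron rows. CYP1B1, a cytochrome P450 gene of oestrogen and xenobiotic metabolism (chromosome 2, 38066973 to 38109902), fell from 258 ± 17.8 to 109 ± 6.88 CPM and MMP1 from 105 ± 1.73 to 50.8 ± 2.72. In all, 593 genes were called, 254 higher and 339 lower, and 51 rose and 31 fell at least 2-fold. Without FH replicate 2, 390 genes were called. At least 2-fold changes numbered 25 with the DESeq2 Wald test and 48 with protein-coding transcript rows alone.

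Of the 18 stress response genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), and the set rose (adjusted p = 4.6e-09). PSAT1 changed by 0.58 ± 0.07, the pseudokinase gene TRIB3 by 0.68 ± 0.08 and SDF2L1 by 0.65 ± 0.12. The member that fell was ATF5 (-0.44 ± 0.09), named after its value was seen. The invasion protease list shifted down (adjusted p = 0.022) and lost its call with an estimated correlation (adjusted p = 0.16), without vector replicate 1 (0.051), without FH replicate 1 (0.12) and without a filter (0.091). Of its 8 members 1 was called, MMP1 at -1.05 ± 0.10, and 2 over the list alone.

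The other 12 tested lists were not called. Of the inflammatory list, 0 of 12 members were called (adjusted p = 0.32), also when adjusted over the list alone. IL1B had 40.5 ± 5.14 CPM with FH. Of the YAP and TEAD list, 2 rose and 1 fell of 19 (adjusted p = 0.60, with 3 and 1 adjusted over the list alone), among them NT5E at 0.52 ± 0.12 and PTPN14 at -0.26 ± 0.04. Its median was 0.03 and its mean -0.0010, and its test pointed up. KRT7 changed by 0.50 ± 0.11 in the luminal list (adjusted p = 0.32; 2 higher adjusted over the list alone), but 0.27 (adjusted p = 0.83) with protein-coding transcript rows alone. In the basal list (adjusted p = 0.34), 1 of 9 members fell, the same number adjusted over the list alone. Its mean was 0.07 and its median -0.07, and its test pointed down. In the mesenchymal list (adjusted p = 0.32), 3 of 13 rose, including the collagen gene COL6A2 at 1.01 ± 0.18 and the intermediate filament gene VIM at 0.47 ± 0.12, with 3 higher and 1 lower adjusted over the list alone. In the androgen receptor list (adjusted p = 0.78), 1 of 4 members rose, NDRG1 (0.88 ± 0.24, 87.2% of counts in retained-intron rows), and 1 fell, with the same counts adjusted over the list alone. Its mean was 0.09 and its median -0.07, and its test pointed down. No member was called in the lists of epithelial junctions (adjusted p = 0.81), interferon (0.32), proliferation (0.34), foregut and liver (0.34; 1 adjusted over the list alone), hypoxia (0.34) and cholesterol synthesis (0.60).

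The largest rises among the named genes were in the angiopoietin gene ANGPT4 (2.63 ± 0.54, to 5.64 CPM), PTGFRN (2.29), PAPPA2 (2.25), FCGBP (2.06), ASNS, ACTL10 (1.73), NAP1L2 (1.61), BEND6 (1.56), the peptide hormone gene UCN (1.41) and JCAD (1.36). Among the largest falls were those of CH25H (-1.46 ± 0.27), CYP1B1 (-1.24 ± 0.08), UXS1 (-1.23, 90.5% of counts in retained-intron rows), CDC123 (-1.19, 100% in such rows), SNX3 (-1.18), MMD (-1.14), LRRC20 (-1.13), HS6ST3 (-1.08) and MMP1. These were picked among genes whose groups did not overlap, as 20.9% of all tested genes did not, against 10% by chance. Among called genes with over 100 CPM, 77 were higher and 191 lower with FH, against 134 higher and 141 lower with the loess offset against abundance.

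Calls of 10 named genes ended, with FH against vector, in some of the 9 fits that left out 1 library. MMD lost its call in 5 fits (highest adjusted p = 0.34, without vector replicate 3), SNX3 in 6 (0.21, FH replicate 2), HS6ST3 in 5 (0.16, FH replicate 2), VIM in 1 (0.11, FH replicate 2), NT5E in 2 (0.11, FH replicate 2) and UXS1 in 2 (0.091, FH replicate 2). ASNS lost it in 1 (0.057, FH replicate 3), LRRC20 in 4 (0.12, vector replicate 2), ACTL10 in 1 (0.062, vector replicate 2) and NDRG1 in 5 (0.094, FH replicate 1). With protein-coding rows alone ASNS (0.19) and VIM (0.43, log2 change 0.74) missed the threshold, as did SNX3 (0.086) and MMD (0.066) without a filter.

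The comparison of FOXA1 with FH libraries tests where these groups differ. Inflammatory genes were lower with FOXA1, IL1B by -3.05 ± 0.20 on the log2 scale (adjusted p = 3.9e-16), IL1A by -2.26 ± 0.38, CXCL1 by -2.23 ± 0.20 and CXCL2 by -0.80 ± 0.21. ANKRD1 was higher with FOXA1 by 1.12 ± 0.05 (adjusted p = 5.4e-23), and G0S2, an inhibitor of lipolysis (chromosome 1, 209675412 to 209676390), stood at 141 ± 8.90 CPM with FOXA1 against 473 ± 42.7 with FH (SD, n = 3). In all, 575 genes were called, 309 higher and 266 lower with FOXA1, and 41 and 75 differed at least 2-fold. Without FH replicate 3, 376 genes were called, and with the DESeq2 Wald test 75 differed at least 2-fold.

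The inflammatory list was lower with FOXA1 (adjusted p = 3.1e-10), with 0 of 12 higher and 4 lower, or 1 and 4 adjusted over the list alone. The YAP and TEAD list was higher (adjusted p = 1.7e-07), with 5 of 19 higher and 1 lower, or 7 and 2 adjusted over the list alone, including CCN2 at 0.54 ± 0.04, CRIM1 at 0.41 ± 0.05 and the coagulation initiator F3 at 0.53 ± 0.10 (0.83 with protein-coding transcript rows alone). The hypoxia list was lower (adjusted p = 5.4e-05), with 4 of 17 lower, or 5 adjusted over the list alone, namely VEGFA at -1.65 ± 0.12 (98.8% of counts in retained-intron rows), PFKFB4 at -0.69 ± 0.12, PDK1 at -0.56 ± 0.14 and KDM3A at -0.56 ± 0.16. With protein-coding transcript rows alone the hypoxia list had adjusted p = 0.13. The invasion protease list was lower (adjusted p = 0.037), a call lost with an estimated correlation (adjusted p = 0.13). Of its 8 members 2 were lower, or 3 adjusted over the list alone, among them MMP3 at -2.94 ± 0.64 and the urokinase receptor PLAUR at -0.61 ± 0.18. That call was lost in 7 of 9 fits that left out 1 library, all but those without vector replicate 3 or FH replicate 1, with adjusted p up to 0.12 without FOXA1 replicate 2, and with protein-coding rows alone (0.058).

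The other 10 lists were not called between FOXA1 and FH. Members that differed were KRT7 (0.65 ± 0.10, luminal list adjusted p = 0.29), CAV2 (0.44 ± 0.09, basal 0.99), CLDN1 (0.87 ± 0.08) and DSP (0.57 ± 0.15, epithelial junctions 0.062), and, among 1 higher and 1 lower mesenchymal members, COL6A2 (-1.14 ± 0.18, mesenchymal 0.35). So did NDRG1 (-1.85 ± 0.26, 87.2% of counts in retained-intron rows, androgen receptor 0.085), and CEBPB (-0.58 ± 0.05) and TRIB3 (-0.36 ± 0.08) among 3 lower members of the stress response list (adjusted p = 0.11). KRT7 had 1.19 (adjusted p = 0.11) with protein-coding transcript rows alone. The lists for interferon (adjusted p = 0.085), proliferation (0.74), foregut and liver (0.96) and cholesterol synthesis (0.99) had no called member, also when adjusted over the list alone. The median of the proliferation list was 0.06 and its mean -0.02, and its test pointed up. Adjusted over the list alone, 1 luminal member was higher and 1 lower, with 2 and 2 basal and 4 and 1 epithelial, and the mesenchymal, androgen receptor and stress lists kept their counts. The epithelial list gained a call in 6 of 9 fits that left out 1 library, those without vector replicate 2 (0.024) or 3 (0.025), FOXA1 replicate 2 (0.0059) or 3 (0.027), or FH replicate 1 (0.031) or 3 (0.024). Interferon gained one without FOXA1 replicate 1 (0.022) or FH replicate 3 (0.027), and the androgen receptor list without FH replicate 3 (0.0497). Without a filter interferon (0.026) and the androgen receptor list (0.0097) gained one. So did the epithelial list in the fit of 6 libraries (0.021) and with the loess offset (0.044), and the stress list with that offset (0.028).

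The named genes highest in FOXA1 relative to FH were SHANK2 (2.82, 31.2% of counts in retained-intron rows), RTN4RL1 (2.33), F2RL2 (2.13 ± 0.18), INHBB (1.79 ± 0.12), C4BPB (1.73, 90.2% in such rows), TOX (1.71), TTC9 (1.54), WASHC1 (1.53), ATOH8 (1.37) and LAMP3 (1.37). The lowest with at least 5 CPM in the higher group were SIRPB1 (-3.37), IL1B, CD82 (-2.50), BCYRN1 (-2.48) and SHISAL1 (-2.40). IL1A, CXCL1, PTGFRN (-1.90), NDRG1 and G0S2 (-1.75 ± 0.07) followed. BCYRN1, a non-coding RNA with similar copies in the genome, stood at 45.1, 13.4 and 11.6 CPM in the FH libraries, had adjusted p = 0.078 with the DESeq2 Wald test and a log2 difference of -1.59 without FH replicate 1, and is uncertain. Of all tested genes 19.9% had groups without overlap, against 10% by chance. Calls of 6 named genes ended in some of the 9 fits that left out 1 library, PLAUR in 4 (highest adjusted p = 0.35, without FH replicate 3), PDK1 in 2 (0.14, FH replicate 3), KDM3A in 4 (0.25, FOXA1 replicate 3), WASHC1 in 3 (0.15, FOXA1 replicate 1), CXCL2 in 3 (0.12, FH replicate 2) and DSP in 3 (0.11, FH replicate 2). KDM3A missed the threshold without a filter (0.056) and PLAUR with the loess offset (0.0502).

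Across the 12578 genes, changes with FOXA1 and with FH against the same vector libraries correlated with r = 0.51 and had a covariance of 0.108, or 0.0570 among genes of at least 5 CPM. Genes are not independent replicates. In 50 simulations of unchanged groups against those libraries, 11913 to 12013 genes passed the filter, and observed and simulated values were compared over those same genes, a choice made after seeing the data. Over them r was 0.49 observed and 0.50 simulated. The covariance was 0.0876 observed and 0.0578 simulated, a difference of 0.0298 (0.0257 to 0.0334 over the simulations). Among those of at least 5 CPM r was 0.56 observed and 0.50 simulated, and the covariance 0.0566 and 0.0214, a difference of 0.0352. Among called genes 123 were higher in both groups, against 7.90 for independent lists, and 132 were lower in both, against 12.1. Those expected numbers leave out the shared vector libraries. The simulated groups shared 0 calls, but had hardly any calls to share, on average 0.02 higher and 0.08 lower for FOXA1, so this 0 measures no chance overlap. Part of the overlap may come from the shared vector libraries. Separate vector libraries, 1 for one comparison and the other 2 for the other in a fit with 4 groups, were tried in 6 splits after seeing the data, with the lone library assumed to vary like the rest. The covariance was then 0.0322 to 0.0504 and r 0.09 to 0.15, and 27 to 65 genes were higher in both groups and 36 to 93 lower, against 1.24 to 6.96 and 2.24 to 10.3 for independent lists. A trait common to all 3 vector libraries stays shared in such splits. With all 3 vector libraries in both comparisons, a further 16 genes were called in opposite directions.

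**Figure D3:**
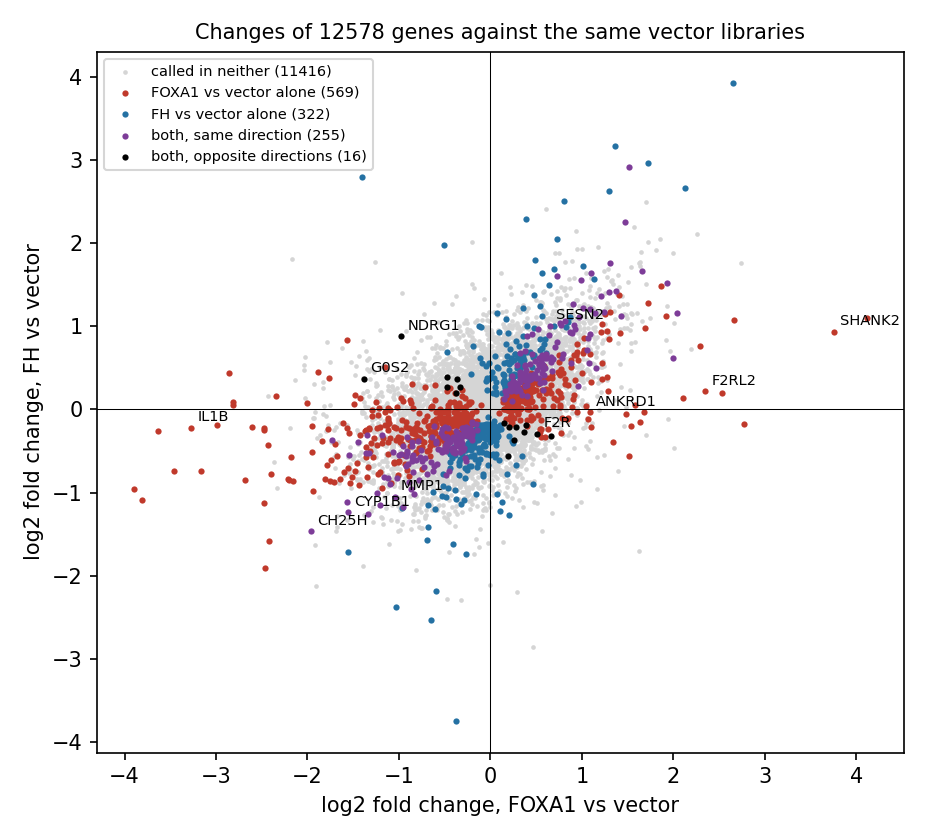
Each point is 1 of 12578 genes, with the log2 fold change of FOXA1 against vector on the x axis and of FH against vector on the y axis, coloured by where it was called. Of the genes called in both comparisons, 255 changed in the same direction and 16 in opposite directions, and IL1B, ANKRD1 and F2RL2 lie near the horizontal axis.

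Few genes under 1 CPM in every vector library, here termed silent, were called higher, here termed switched on. CPM covers only countable bases, so a gene under 1 CPM need not be silent. The simulation drew no gene at 2 CPM or less, so the power for such genes is unknown. SHANK2 rose from 0.904 to 12.4 CPM with FOXA1 but lay outside this rule, with 1.16 CPM in vector replicate 1. The counts below therefore do not show how many silent genes were activated. With FOXA1, 2 genes under 1 CPM in every vector library were called higher, the pseudogene GAS2L1P1 and a locus without an assigned symbol (named after their values were seen), and 17 genes were under 1 CPM in every FOXA1 library and called lower. These counts changed when single libraries were left out. Without vector replicate 1, 2 or 3 the counts switched on were 6, 4 and 8, and those switched off 8, 7 and 9. Leaving out a vector library also eases the rule for genes switched on, as fewer libraries must be under 1 CPM. Those rises therefore do not show that a particular vector library mattered. Without FOXA1 replicate 2 or FH replicate 1, 1 and 4 were switched on. With FH, 5 were switched on, GNAZ, MAN1C1, SORCS2, STK4-DT and an unnamed locus, and 3 were switched off, HRCT1 and a pair of unnamed loci (all named after their values were seen). Without vector replicate 1, FH replicate 2 or FH replicate 3, 3, 1 and 2 were switched on. At 0.5 CPM in place of 1, the counts were 1 on and 6 off with FOXA1, and 2 on and 1 off with FH.

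Most markers of other cell types were near the floor. How many of their bases could be counted is not given here, so a low count need not mean an absent transcript. Of 20 blood and endothelial markers 1 could be tested, the adhesion molecule gene PECAM1, with 6 to 33 counts per library. PECAM1 fell with FOXA1, from 4.22 ± 0.806 to 1.31 ± 0.297 CPM, a log2 change of -1.67 ± 0.48 (adjusted p = 0.022; lost in 4 of 9 fits that left out 1 library, at most 0.101, without vector replicate 2), and had -0.56 ± 0.43 with FH (adjusted p = 0.60). The list summed to 153 counts with vector, 83 with FOXA1 and 116 with FH. Of 16 fibroblast and adipocyte markers 1 could be tested, FBLN1, with 61 to 138 counts per library and log2 changes of 0.40 ± 0.19 with FOXA1 (adjusted p = 0.26) and 0.51 ± 0.19 with FH (adjusted p = 0.13), not called. That list summed to 259, 338 and 376. Neither list was tested as a set.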

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

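Of the tests below, the lean in the FOXA1 libraries, the retained-intron tests, the length of countable stretches, the test of a single vector library over all 4 mitochondrial genes, the MT-ND5 and MT-ND6 differences between FOXA1 and FH, and the loess offset itself were chosen after the result was seen.

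Looked at more closely were the 16 genes called against vector in both groups, in opposite directions. Their number was not set beside that for independent lists, so no excess is shown. Their difference between FOXA1 and FH, given below, was called in all 16 in edgeR, but follows from that choice and adds no support. Lower with FOXA1 and higher with FH were G0S2 (log2 difference -1.75), NDRG1 (-1.85, 87.2% of counts in retained-intron rows), LRRN1 (-0.86), the laminin gene LAMA5 (-0.75), IER5L (-0.72), IRF2BPL (-0.60) and CEBPB (-0.58). Higher with FOXA1 and lower with FH were RNF144B (0.98), the thrombin receptor gene F2R (0.80) and its relative F2RL1 (0.76), SH3RF1 (0.64), CLCN4 (0.62), PLXNA2 (0.58), the phosphatase gene DUSP1 (0.49), RBMS2 (0.42) and MTND2P28 (0.32), a nuclear copy of mitochondrial sequence whose reads are uncertain. G0S2, IRF2BPL, F2R, DUSP1 and RBMS2 kept both calls in all 9 fits that left out 1 library, and the other 11 lost a call, with FOXA1 NDRG1 in 5 (adjusted p up to 0.15, without FOXA1 replicate 3), F2RL1 in 5 (0.13, vector replicate 2), CLCN4 in 4 (0.12, vector replicate 2) and MTND2P28 in 4 (0.35, FOXA1 replicate 2, log2 change 0.10 in place of 0.15), and with FH NDRG1 in 5 (0.094, FH replicate 1), PLXNA2 in 8 (0.20, vector replicate 1), RNF144B in 7 (0.14, vector replicate 3), SH3RF1 in 4 (0.14, vector replicate 3), LAMA5 in 3 (0.21, FH replicate 3), LRRN1 in 3 (0.12, FH replicate 1), IER5L in 1 (0.0504, vector replicate 1), CEBPB in 1 (0.054, FH replicate 1) and MTND2P28 in 4 (0.33, FH replicate 3, -0.11 in place of -0.17).

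Called genes above 100 CPM leaned lower with FH, with 191 of 268 lower (71.3%). Vector libraries that stand apart would give the same lean with FOXA1, unless a response to FOXA1 offset it. With FOXA1 45.6% were lower, which cannot decide for that reason. No single library carried the lean, since the lowest share without 1 of the 6 libraries was 66.7%. A loess offset against abundance brought the share to 51.3%, but such an offset centres every abundance range by construction and would remove a real shift as well, so this test decides nothing, and the bound set for it beforehand was wrong for that reason. A scaling trend, vector libraries that stand apart and a response of abundant genes to the FH construct cannot be told apart here.

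Of the calls, 46 with FOXA1 and 25 with FH were in genes with over 60% of their counts in retained-intron rows. If intron-containing RNA alone had changed, the other exon rows would show no shift. In such genes picked on retained-intron rows alone and with at least 50 counts elsewhere, the median log2 change of the other rows, signed by that of the retained-intron rows, was 0.0476 with FOXA1 (95% bootstrap interval -0.15 to 0.60, 11 of 19 genes in the same direction) and 0.0073 with FH (-0.20 to 0.22, 7 of 14), against 0.61 and 0.51 in the retained-intron rows, while a first version, replaced after its result was seen because it picked genes on all rows together, gave 0.39 and 0.23. These medians decide nothing, since the other rows moved with the retained-intron rows by at least 0.5 times their change in 7 and 3 of the genes, among them ECI1 (0.88 against 0.90), GAS5 (0.67 against 0.69), NVL (0.68 against 0.61) and SLC37A2 (-1.36 against -1.08) with FOXA1 and ASNS (1.41 against 1.95) with FH, and in others against them, as in NARS2 with FOXA1 (0.38 against -1.04) and TFPI with FH (-0.61 against 0.55), all named after their values were seen. A change of intron-containing RNA alone and a change of the whole gene cannot be told apart over these genes; VEGFA and NDRG1 were not among them, and no biological explanation was tested.

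The mitochondrial genes MT-ND5, MT-ND6, MT-RNR1 and MT-RNR2 were lower than with vector in both groups, with log2 changes of MT-ND6 of -0.60 ± 0.04 with FOXA1 and -0.38 ± 0.04 with FH, whereas MT-ATP8 (0.52 ± 0.11 and 0.96 ± 0.11), MT-ND2 (0.24 ± 0.03 and 0.10 ± 0.03) and MT-ATP6 (0.15 ± 0.03 and 0.13 ± 0.03) were higher in both, although MT-ATP8 lost its call with FOXA1 without FOXA1 replicate 3 (0.25, adjusted p = 0.14) and MT-ND2 with FH in 3 of 9 fits that left out 1 library (at most 0.23, without FH replicate 1, where its change was 0.06). A single vector library does not account for the calls of the 4 lower genes, since the highest adjusted p without 1 vector library was 3.1e-06 for MT-ND6 and 0.0098 over the 4, although without vector replicate 3 the log2 change of MT-RNR2 with FOXA1 was -0.10 in place of -0.16. Short countable stretches stay open, since the median of the 4 genes was 1256.5 bases (525 to 1812) against 783 (161 to 1542) in the other 11, with overlapping ranges and MT-ND6 the shortest of the 4. Because the counting ignored strand, MT-ND6 counts may include reads from the opposite strand. How poly(A) selection affected the 4 genes was not tested. A vector culture that stands apart would leave FOXA1 and FH alike. It cannot be the whole of the change in MT-ND6 counts, which differed between them by -0.22 ± 0.04 (adjusted p = 5.6e-04). MT-ND5 differed by -0.0391 on the log2 scale, which such a culture and a response shared by both constructs would each give, and for that gene these cannot be told apart without another vector line.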

How the results depend on the processing

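Protein-coding rows alone, leaving out mitochondrial genes, the loess offset, similarity over the genes that passed the filter in each simulation and similarity with separate vector libraries were chosen after seeing the data. Small changes of low genes are often missed at this depth. Of 119 calls of genes under the naming rule, 92 held in every fit that left out 1 library, and 0 reversed in those fits. DESeq2 size factors and leaving FOXA1 and FH out of the counts changed no list call and moved no count of called genes by over 1.5 times. When 1 library was left out, the fitted change of the gene FH, not called, ranged from -0.11 (without FOXA1 replicate 1) to 0.14 (vector replicate 3) with FOXA1 and from -0.32 (vector replicate 1) to -0.07 (FH replicate 2) with FH. Apart from the lower number of genes tested with protein-coding rows, the cause of the shifts below was not tested. Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated from -0.0203 to 0.0151, and not every library correlated best with its own number. With the replicate block 795, 554 and 545 genes were called for FOXA1 against vector, FH against vector and FOXA1 against FH, no list call changed, and TIMP2 (0.063), CEBPA (0.058) and SNX3 (0.056) missed the threshold.

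DESeq2's Wald test called 25 genes at least 2-fold for FH against vector and 75 for FOXA1 against FH. With protein-coding transcript rows alone, where 6522 genes were tested, the 2-fold counts were 116 (FOXA1 against vector) and 48 (FH against vector), and the lists called 4 (FOXA1 against vector) and 2 (FOXA1 against FH). Lists that then lost their call had adjusted p of 0.57 (luminal), 0.23 (epithelial junctions), 0.33 (interferon), 0.35 (androgen receptor) and 0.35 (hypoxia) with FOXA1, and 0.058 (invasion) and 0.13 (hypoxia) for FOXA1 against FH. Without a filter, luminal (0.065), epithelial junctions (0.24) and hypoxia (0.058) with FOXA1 and invasion with FH (0.091) lost their call, which left 1 list with FH, and interferon (0.026) and androgen receptor (0.0097) gained one for FOXA1 against FH. In camera with an estimated correlation, luminal (0.079), epithelial junctions (0.105) and androgen receptor (0.105) with FOXA1 lost their calls. So did invasion with FH (0.16), which left 1 list, and invasion for FOXA1 against FH (0.13). The estimates for these lists, in the same order, were -0.019, 0.0091, -0.112, -0.112 and -0.094. All lay below the preset 0.01, so a correlation above the preset does not account for these losses. Androgen receptor with FOXA1 had 0.060 in the fit of 6 libraries and 0.066 without mitochondrial genes. For FOXA1 against FH, epithelial junctions gained a call in the fit of 6 libraries (0.021) and with the loess offset (0.044), as did the stress response with the offset (0.028). Among genes of at least 5 CPM the covariance of the responses was 0.0570. With separate vector libraries, as a mean of 6 splits, it was 0.0460 over all genes, r was 0.14, and 40.3 genes were higher and 60.7 lower in both groups. With silence at 0.5 CPM, 1 gene was switched on and 6 off with FOXA1, and 2 on and 1 off with FH.

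Leaving out 1 library gave 559 to 832 calls for FOXA1 against vector, 390 to 589 for FH against vector and 376 to 669 for FOXA1 against FH, and 1 to 2 lists with FH. Genes switched on ranged from 1 to 8 and off from 7 to 15 with FOXA1, and on from 1 to 7 with FH. Adjusted p with FOXA1 ranged from 0.0078 to 0.101 (luminal), 0.018 to 0.125 (epithelial junctions), 0.00066 to 0.055 (interferon) and 0.044 to 0.137 (androgen receptor), and with FH from 0.011 to 0.122 (invasion). For FOXA1 against FH it ranged from 0.031 to 0.119 (invasion), 0.0059 to 0.171 (epithelial junctions), 0.022 to 0.305 (interferon) and 0.0497 to 0.191 (androgen receptor).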

Other observations

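The genes and families in the first 2 paragraphs were chosen after their values were seen. Of 3 protease-activated receptor genes tested, 3 rose with FOXA1 and 2 fell with FH, also with DESeq2 size factors and the loess offset. F2RL2 changed by 2.35 with FOXA1, F2R by 0.51 with FOXA1 and -0.29 with FH, and F2RL1 by 0.19 and -0.57. The 3 genes lie close together on chromosome 5, starting at 76615482 (F2RL2), 76716126 (F2R) and 76818933 (F2RL1). They may therefore not be independent of each other. Of 23 histone genes, 6 fell and 0 rose with FOXA1 (7 fell with the loess offset), and 4 fell and 1 rose with FH under all 3 scalings. H2BC12 changed by -0.49 with FOXA1 and -0.46 with FH, and H1-2 by -0.76 and -0.48, each uncertain because histone genes are similar. How poly(A) selection affected the counts of histone genes was not tested, so lower counts need not mean less histone RNA. In fits that left out 1 library F2RL1 lost its call with FOXA1 in 5 of 9 (adjusted p up to 0.13, without vector replicate 2) and H1-2 with FH in 2 (0.16, without vector replicate 1).

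Other abundant genes outside the lists moved with FOXA1. The transcription factor gene SOX9 changed by -1.35 (adjusted p = 3.5e-18), the Wnt receptor gene FZD1 by -1.10 (6.6e-18), the pattern recognition gene PTX3 by -1.16 (1.6e-20), the cystine transporter gene SLC7A11 by 0.73 (7.5e-16) and the keratin gene KRT81 by 0.96 (7.5e-16), uncertain because similar keratin genes exist. With FH, SOX9 changed by -0.31, PTX3 by -0.82 and KRT81 by 0.29, all called, and FZD1 had -0.16 (adjusted p = 0.15) and SLC7A11 0.12 (adjusted p = 0.19), not called. The calls with FH of SOX9 (0.057, without FH replicate 1) and KRT81 (0.053, without vector replicate 3) each ended in 1 of 9 such fits.

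Fewer genes had a count in the FOXA1 libraries. Thinned to 5659271 counts each, FOXA1 libraries had 20024 to 20194 genes with a count, vector libraries 20453 to 20849 and FH libraries 20729 to 20957. The difference was not tested.

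With 3 libraries against 3 there are 10 splits of the 6, the real 1 included, too few for a share under 0.05. For FOXA1 against vector the real split gave 840 calls and the highest other 0, 185 and 0 at least 2-fold, and 9 and 2 lists. For FH against vector it gave 593 and 0, 82 and 0, and 2 and 1. For FOXA1 against FH it gave 575 and 1, 116 and 1, and 4 and 2.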
